A study of Mus musculus with 6 samples.

How the data were processed

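Bone marrow cells of adult wild-type mice were cultured with M-CSF at 20 ng/mL for 6 days, then exposed for 48 h to Mafb lentivirus or mCherry control lentivirus at a multiplicity of infection of 30, followed by 6 days in medium with M-CSF, per the labels' protocols. Poly(A) RNA was selected, second strands were marked with dUTP and removed, and paired reads were sequenced, per the labels' protocols. The deposited values are FPKM, a measure of fragments corrected for transcript length and library total, given by the authors for each Ensembl gene and library. The submitters' processing notes name fastp, StringTie and edgeR and the genome build GRCm39, with no versions and no roles. The aligner, the annotation release and the strand setting are not given in the sources used here. Coordinates and gene names are those of the deposited table. Every row had a value above 0 in at least 1 library.

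FPKM already divides by gene length and by library total, so a few abundant transcripts can shift all the others, and genes sharing reads with near-identical copies (Gapdh and its pseudogenes, mitochondrial genes and their nuclear copies) are uncertain. No read counts are in the table, so no test on counts was made and the depth in reads is unknown. A relative depth per library was taken from 6121 single-exon genes with 1 transcript. It used the most frequent low value of FPKM times transcript length within a fixed window, read as 1 fragment. The spread between libraries of 1 group was 1.64 to 1.91 times that expected from sampling among the libraries labelled Mafb, 2.68 between control libraries 2 and 3, and 6.25 and 6.69 between control library 1 and these. No pair agreed within sampling noise, and each library was counted once. Because the labels do not say that libraries came from different animals, p-values measure the spread between these libraries.

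Groups were taken from the sample titles, and the 6 value columns from the library names in the labels. Genes with a mean of at least 0.5 FPKM over the 6 libraries (12152 of 24938) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, as a moderated test with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is the difference of group means on this scale, and understates the change of low genes. Values are means with SD over 3 libraries unless an SE is named. Gene lists were tested with camera (preset inter-gene correlation of 0.01), adjusted by Benjamini-Hochberg over the 23 lists with at least 5 tested members, out of 32; none of the calls held when the correlation was estimated from the data. With 3 libraries per group that estimate is imprecise. For p53 targets (-0.061) and macrophage identity (-0.0067) it lay below the preset value of 0.01. Members that move together therefore do not account for the loss of those calls. Of 565 list entries 496 matched a symbol in the table, 20 matched an older symbol through the gene identifier in an older annotation used for names alone, and 49 had no row. Where a symbol had several rows, the one with the highest mean was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the figures.

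The groups, the tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule takes Mafb; the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap, without predicted genes and clones; up to 4 called members of each list (2 for lists of other cell types and for technical lists), or else its 2 highest members; and 26 genes given whatever their result. Members behind a count of 5 or fewer, the Mcm genes and the genes that open the other observations were named after their values were seen. Alternatives were pseudocounts of 0.1 and 0.01, no filter and a mean of at least 5 FPKM, median-of-ratios and quantile scaling, no intensity trend, the replicate number as a block, leaving out each library, a threshold of 0.01, an estimated correlation, and the rotation test fry. Added after seeing the data were a loess adjustment of each library for GC content and transcript length (98.7% of tested genes had both), a test of the KEGG pathways in the table, and lists of G2/M and G1/S genes outside the fixed cell cycle list.

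The test was tried on simulated libraries with the means and spread of the 12152 genes in this comparison. It recovered 24% of genes changed by 0.3 on the log2 scale, 92% at 0.6, 96% at 1 and 100% at 2, with 10 unchanged genes called. The 50 genes changed at each size all had a mean above 2 on the log2(FPKM + 1) scale, so recovery among lower genes was not tried. Fewer genes were changed than were called in the data, and each gene had the same simulated spread in both groups. Camera called the 1 list that was shifted and 0 of 20 unchanged lists. Genes were simulated independently of each other and put in lists at random. That trial therefore does not show how the preset correlation does for lists whose genes move together. Estimated correlations in the data reached 0.561 for the interferon response list and 0.954 for the cell cycle list.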

Results

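The data were 6 poly(A) RNA-seq libraries of mouse bone marrow-derived macrophages, cells grown from marrow with M-CSF, the growth factor that drives macrophage differentiation. One group of 3 libraries came from cells given a lentivirus carrying Mafb, a transcription factor of the macrophage lineage, and the other 3 from cells given an mCherry control lentivirus. The series' design text calls the 3 libraries of each group biological replicates, without saying whether they came from different animals. Values were FPKM for 24938 Ensembl genes. They summed to between 298052 and 307940 per library, with 19311 to 20772 genes above 0. Read totals were not analysed here. The most frequent low values put relative depth at 1.00 in control library 1, 1.05 to 1.18 in the libraries labelled Mafb, and 1.38 in control library 2. The question of the design was which transcripts differ when Mafb is overexpressed.

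The Mafb transcript itself was nearly level between the groups. The gene (ENSMUSG00000074622) lies on the minus strand of chromosome 2 from 160205623 to 160208985 in GRCm39 and has no introns, so its transcript and its genomic span coincide. It measured 117, 119 and 115 FPKM in the libraries labelled Mafb 1, 2 and 3, against 112, 104 and 112 FPKM in control libraries 1, 2 and 3. The libraries labelled Mafb were higher in 3 of 3 cases, by a log2 fold change of 0.10 (95% interval -0.01 to 0.21), a ratio of 1.07 with an interval of 0.991 to 1.15. This did not pass the threshold (limma, Benjamini-Hochberg adjusted p = 0.164). With library values adjusted for GC content and transcript length, an alternative chosen after seeing the data, it was 0.17 with adjusted p = 0.037. That adjustment also moved the median over all genes in the fit up, from -0.04 to 0.02. The Mafb row therefore checks the group labels only weakly, and every direction given here is between libraries as labelled. Maf, a related transcription factor, measured 25.7 ± 0.866 FPKM (SD, n = 3) in the libraries labelled Mafb and 29.4 ± 1.45 in controls, and fell by 0.18 on the log2 scale (limma, adjusted p = 0.0445). That call was lost without any 1 library except control library 1, with adjusted p between 0.0695 and 0.153, and with median-of-ratios scaling (0.0793), quantile normalization (0.0951) and the GC content and length adjustment (0.0966).

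In the libraries labelled Mafb, more members of the interferon response, inflammatory, cell cycle and macrophage identity lists fell than rose, and more members of the cholesterol synthesis list rose than fell. The largest increases were in Cdkn1c, an inhibitor of cyclin-dependent kinases (chromosome 7, 143012076 to 143014787), at 89.2 ± 4.01 against 15.5 ± 8.38 FPKM (log2 fold change 2.57 ± 0.31, SE), and in the chemokine receptor Ccr1, at 42.6 ± 1.82 against 8.00 ± 1.16. Next came Cd5l, a secreted scavenger receptor family protein (log2 fold change 2.26), Itgax (1.73), the fatty acid transporter Cd36 (1.64), the monoacylglycerol lipase Mgll (1.62), the desaturase Scd2 (1.61), coagulation factor F7 (1.52), the macrophage elastase Mmp12 (1.45) and transferrin, Trf (1.43). The largest decreases were in the formyl peptide receptor Fpr1 (chromosome 17, 18096733 to 18104202), from 37.3 ± 9.0 FPKM in controls to 0.766 ± 0.230 (log2 fold change -4.42 ± 0.19, SE), and in the acute-phase protein Saa3, from 21.7 ± 4.33 to 0.346 ± 0.0790 (-4.06). Ly6a (-3.86), complement C3 (-3.83), the itaconate-producing enzyme Acod1 (-3.80), Ifi27l2a (-3.68), the chemokine Ccl5 (-3.58), the scavenger receptor Marco (-3.37), cyclin Ccnb2 (-3.17) and Fpr2 (-3.06) followed. By the rule that chose them, each of these 20 genes passed the threshold and lay above, or below, the controls in all 3 libraries. Their limma adjusted p lay between 7.67e-07 and 0.00894.

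**Figure D1:**
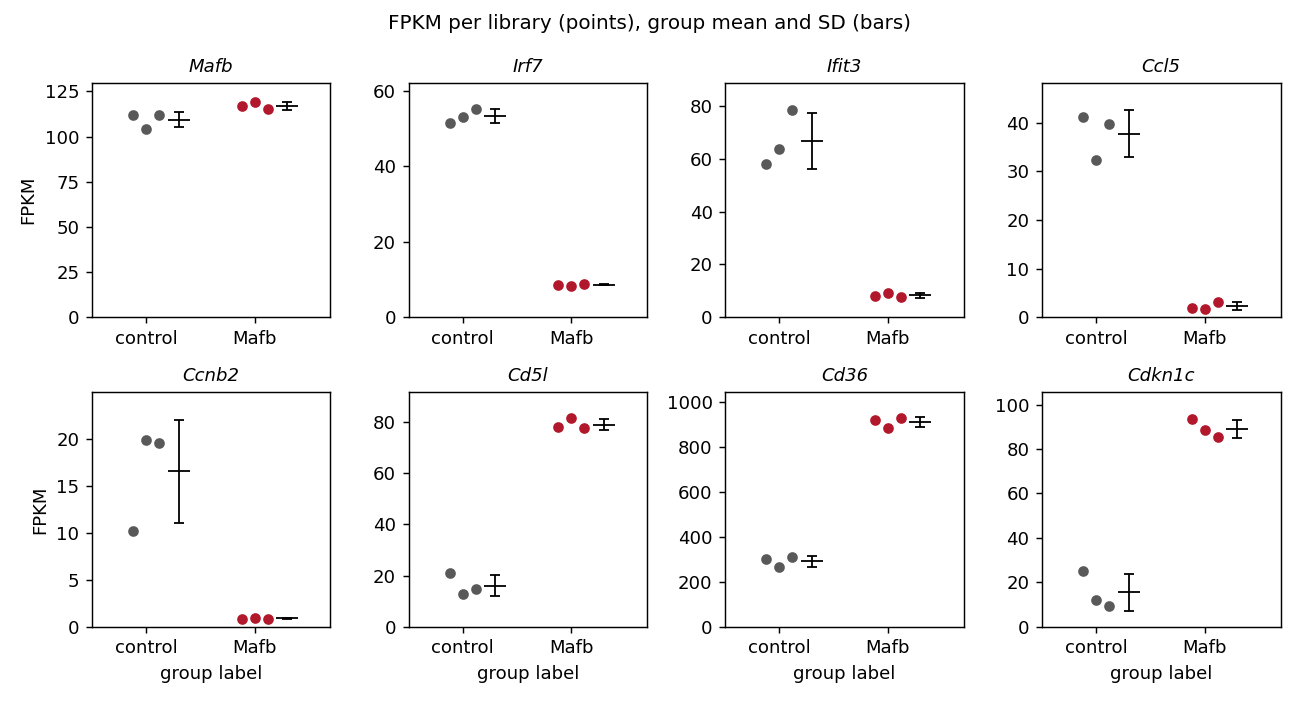
FPKM of 8 genes in each library, on linear axes from 0; points are the 3 libraries of each labelled group and bars the mean with its SD. Mafb is nearly level at 104 to 119 FPKM in the 6 libraries, while Irf7, Ifit3, Ccl5 and Ccnb2 are lower and Cd5l, Cd36 and Cdkn1c higher in all 3 libraries labelled Mafb.

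Of 12152 genes with a mean of at least 0.5 FPKM, 1294 were higher and 2095 lower in the libraries labelled Mafb at an adjusted p under 0.05 (limma on log2(FPKM + 1), Benjamini-Hochberg). Folds on that scale understate the changes of low genes; 51 genes were at least 2-fold higher and 322 at least 2-fold lower. With a pseudocount of 0.1 these became 112 and 532. In 5764 genes (47.4%) the groups did not overlap, where chance gives 10%. The balance of directions depended on how libraries were scaled: 38.2% of the called genes were higher as deposited, 49.0% with median-of-ratios scaling (1690 higher, 1760 lower) and 57.3% with quantile normalization (2057 higher, 1534 lower). The adjustment for GC content and length gave 55.4% (2017 higher, 1626 lower). Without any 1 of the libraries labelled Mafb, 665 to 715 genes were higher and 1341 to 1393 lower, and without control library 3, 856 were higher. Control library 1 stood apart from the other controls, separated from them by the second principal component (15.4% of the variance), while the first (68.7%) separated the labelled groups.

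Interferon-induced transcripts fell together. All 28 tested members of the interferon response list fell, also 28 when adjusted over the list alone, with a median log2 fold change of -1.59. Irf7, the transcription factor that amplifies the interferon response, went from 53.2 ± 1.83 FPKM in controls to 8.58 ± 0.159 (SD, n = 3; log2 fold change -2.50 ± 0.05, SE, limma adjusted p = 1.7e-06). The antiviral effectors Ifit3 (66.7 to 8.31 FPKM), Ifit2 (45.4 to 6.73) and Ifit1 (22.5 to 3.40) fell as well. The list was lower than other genes with camera's preset correlation (Benjamini-Hochberg adjusted p = 1.5e-20), but had adjusted p = 0.309 with an estimated correlation. Leaving out single libraries left 26 to 28 members called.

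Among inflammatory cytokine and NF-kB genes, 7 of 17 tested members fell and 1 rose (9 and 3 when adjusted over the list alone), with a median of -0.56. Ccl5 went from 37.8 ± 4.81 to 2.29 ± 0.781 FPKM, the pattern receptor Tlr2 from 45.4 ± 4.31 to 13.3 ± 1.00, and the NF-kB regulators Nfkbiz (5.85 to 1.78) and Nfkbia (50.2 to 24.3) fell too. The member that rose, Tnfaip3, is an inhibitor of NF-kB signalling (9.35 to 13.9 FPKM); it and the other members named for counts of 5 or fewer were chosen after their values were seen. Tnf measured 16.7 ± 1.85 against 24.4 ± 9.62 FPKM (log2 fold change -0.45, limma adjusted p = 0.254). Camera gave adjusted p = 0.0083 for the list, and adjusted p = 0.419 with an estimated correlation. Control library 1 had the lowest mean of this list among controls, at 3.27 on the log2(FPKM + 1) scale against 3.99 and 3.83, and the libraries labelled Mafb had 2.78 to 2.92. Without control library 1, 13 members were lower, 2 were higher (2 also without Mafb library 2 or with median-of-ratios scaling, 3 with quantile normalization), and Tnf had a log2 fold change of -0.77 (adjusted p = 0.00696).

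Several transcripts of mitosis were lower in the libraries labelled Mafb. In the cell cycle list 18 of 30 members fell and 1 rose (19 and 2 when adjusted over the list alone), with a median of -1.65. Cyclin Ccnb2 went from 16.5 ± 5.50 FPKM in controls to 0.869 ± 0.0369, the mitotic kinase Plk1 from 12.9 ± 5.13 to 1.25 ± 0.279, the kinesin Kif20a from 8.71 to 0.809 and the anaphase activator Cdc20 from 9.85 to 1.03. Pcna, the DNA polymerase clamp, rose from 128 to 240 FPKM. The replication helicase subunits Mcm2 to Mcm7 had log2 fold changes between -0.01 and 0.66, none past the threshold. The list had camera adjusted p = 1.2e-04, and adjusted p = 0.798 with an estimated correlation. The broader KEGG cell cycle pathway, looked at after the data were seen, had 11 of 145 genes higher and 44 lower (12 and 48 when adjusted over the list alone) and was not called (camera adjusted p = 0.258). In control library 1 the mean over the list was 2.81 on the log2(FPKM + 1) scale, between the other controls (3.72 and 3.55) and the libraries labelled Mafb (2.18 to 2.21). Without control library 1, 23 members were lower, and 2 were higher, as also without control library 2.

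Targets of p53, which include brakes on the cell cycle, were also lower: 8 of 12 tested members fell and 1 rose, with the same counts when adjusted over the list alone, and the median was -0.68. Phlda3 went from 20.2 ± 1.02 to 4.09 ± 0.743 FPKM, the apoptosis inducer Bbc3 from 9.70 to 2.34, Trp53inp1 from 10.6 to 3.67 and the cyclin-dependent kinase inhibitor Cdkn1a from 81.5 ± 9.76 to 34.3 ± 0.767. The kinase Plk2 rose from 29.7 to 50.8 FPKM. By camera the p53 list had adjusted p = 5.4e-04, and adjusted p = 0.188 with an estimated correlation.

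Of 6 tested self-renewal factors, Klf2 (22.4 to 3.06 FPKM), Klf4 (2.97 to 1.03) and the polycomb enzyme Ezh2 (3.52 to 1.84) fell, and Jun (36.7 to 43.4) and Bmi1 (12.2 to 14.7) rose; adjusted over the list alone, 3 were lower and 3 higher. Myc measured 18 ± 0.945 against 9.09 ± 4.69 FPKM (log2 fold change 1.04, limma adjusted p = 0.0614). It passed at 0.62 without control library 1 (adjusted p = 0.0117) and at 1.36 without control library 2 (adjusted p = 0.0194), and with median-of-ratios and quantile scaling (0.049 and 0.0455). Ezh2 was no longer called without any 1 library except control library 1 (adjusted p 0.0717 to 0.0936), nor Bmi1 without Mafb library 2 or 3 or control library 3 (0.0552 to 0.0701), nor Jun without any 1 library labelled Mafb or control library 3 (0.0571 to 0.0719). The number of members higher was 1 without Mafb library 1 and 0 without Mafb library 2 or 3 or control library 3. The list as a whole was not called (camera adjusted p = 0.895). Its median was -0.20 and its mean -0.40, while camera's statistic pointed up. The median was -0.32 without control library 1 and -0.12 without control library 2.

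Several transcripts that define macrophages were lower. In the macrophage identity list 11 of 17 tested members fell and 1, Cd68, rose (11 and 1 when adjusted over the list alone), with a median of -0.48. The fractalkine receptor Cx3cr1 went from 28.3 ± 16.4 to 2.18 ± 0.135 FPKM, the lipopolysaccharide co-receptor Cd14 from 189 ± 11.5 to 61.3 ± 1.33, Siglec1 from 85.0 to 28.4, and lysozyme, Lyz2, from 17044 ± 939 to 8726 ± 130. The M-CSF receptor Csf1r fell from 464 ± 16.4 to 306 ± 5.12 FPKM and Adgre1, which encodes F4/80, from 603 ± 10.5 to 314 ± 4.21 (limma adjusted p = 2.8e-04 and 3.9e-05). The list had camera adjusted p = 8.2e-04, and adjusted p = 0.188 with an estimated correlation. Without Mafb library 1 or 3, 7 members were lower, and with median-of-ratios scaling, quantile normalization or the GC content and length adjustment 8 were. The median was -0.19 with quantile normalization. Cd68 was not called without any 1 library except control library 1 (adjusted p 0.0594 to 0.123), and 2 members were higher without control library 1. Lyz2 is the highest transcript of every library, so quantile normalization set it equal in all of them (log2 fold change 0). Without the filter on low values Lyz2 was not called either (limma adjusted p = 0.184), and 6 members of the list were lower.

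Genes enriched in microglia, the macrophages of the brain, were lower in 8 of 9 tested cases, also 8 when adjusted over the list alone, with a median of -0.77. Besides Cx3cr1, the list's Fcrls (named Fcrl2 in the table) went from 55.5 ± 2.74 to 9.58 ± 0.394 FPKM, P2ry12 from 3.35 to 0.759 and Olfml3 from 4.84 to 1.96. For microglia-enriched genes camera adjusted p was 4.5e-05, with adjusted p = 0.309 with an estimated correlation. Cx3cr1, Csf1r and Trem2 are also in the macrophage identity list, and Hexb in the lysosome list, so these lists are not independent. Olfml3 was not called without Mafb library 1 or 3 (adjusted p 0.0537 and 0.0555). Control library 1 had 9.34 FPKM of Cx3cr1 against 38 and 37.5 in the other controls, and 2.03 to 2.30 in the libraries labelled Mafb.

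Markers of other cells were few. All 4 tested monocyte genes fell, too few for a list test: S100a4 from 225 ± 85.4 to 59.4 ± 1.47 FPKM, Ms4a4c from 6.31 to 0.687, Ms4a6b from 19.9 to 9.12 and Hp from 2.16 to 0.125. Both tested dendritic cell markers rose, Itgax from 37.7 ± 9.84 to 125 ± 2.72 FPKM and Batf3 from 0.749 to 1.74. Of 11 listed dendritic cell markers 9 had a row, and those not tested had means of at most 0.1 FPKM. The endothelial marker Kdr rose from 2.05 to 3.79 FPKM (2 endothelial markers higher without control library 1), and the stromal marker Kitl from 1.55 to 2.05, a call lost without any 1 library labelled Mafb or control library 3 (adjusted p 0.0591 to 0.0975). Counts adjusted over each of these lists alone were the same. The neutrophil markers Csf3r (13.8 against 20.9 FPKM) and S100a8 (1.87 against 1.99) did not pass in limma, neither at an unadjusted p under 0.05, although Csf3r did without control library 1 (log2 fold change -0.23, adjusted p = 0.0217). No lymphocyte, erythroid or mast cell marker reached the mean of 0.5 FPKM; the highest mean among them was 0.183 FPKM.

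Many cholesterol synthesis genes rose. Of 22 tested members 16 rose, 6 were not called and 0 fell (18 and 0 when adjusted over the list alone, and by limma at an unadjusted p under 0.05), with a median of 0.45. Squalene epoxidase, Sqle, went from 5.72 ± 1.16 FPKM in controls to 10.9 ± 0.726, Hsd17b7 from 1.90 to 3.85, the low-density lipoprotein receptor Ldlr from 7.20 ± 0.762 to 12.5 ± 0.249 and Msmo1 from 11.2 to 18.9. For cholesterol synthesis camera adjusted p was 8.3e-09, with adjusted p = 0.311 with an estimated correlation. Without Mafb library 3, 10 members were higher.

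Genes of cholesterol efflux and targets of the sterol receptor LXR went both ways. Of 17 tested members 6 rose and 3 fell (7 and 3 when adjusted over the list alone), with a median of 0.26. Scd2 (4.87 to 16.8 FPKM), lipoprotein lipase Lpl (301 ± 33.0 to 654 ± 12) and Apoe (4185 to 6336) rose; Ch25h, which makes 25-hydroxycholesterol (9.84 ± 6.74 to 0.898 ± 0.0531), Apoc2 (10.2 to 5.74) and Npc2 (245 to 208) fell. The efflux transporter Abca1 measured 7.90 ± 0.269 against 8.77 ± 1.80 FPKM (log2 fold change -0.12, limma adjusted p = 0.537). The efflux transporter Abcg1 was among the 6 that rose. Its call was lost without any 1 library labelled Mafb or control library 3 (limma adjusted p 0.0588 to 0.0776). This list had camera adjusted p = 0.0104, adjusted p = 0.381 with an estimated correlation, and adjusted p = 0.12 with quantile normalization. The number that rose was 3 without any 1 library labelled Mafb or control library 3, and 11 without control library 1, while 1 fell without any of the first 4. Apoe was not called without those 4 libraries in turn (adjusted p 0.068 to 0.0773) or with quantile normalization (log2 fold change 0.06), nor Ch25h without any 1 library except control library 1 (0.0536 to 0.0781), nor Npc2 without the same 4 (0.0742 to 0.106).

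Scavenger receptors and genes for clearing dead cells also split. Among 13 tested scavenger receptors 7 rose and 4 fell (7 and 6 when adjusted over the list alone): Cd36 (292 ± 24.8 to 912 ± 22.5 FPKM), Cd5l (16.1 ± 4.23 to 79.0 ± 2.12) and the beta-glucan receptor Clec7a (287 to 584) rose, whereas Marco (11.6 ± 4.16 to 0.171 ± 0.0664), Stab1, Scarb2 and Scarf1 fell. Msr1 rose from 82.9 ± 14.9 to 109 ± 2.25 FPKM at the edge of the threshold (limma adjusted p = 0.0498), and not without any 1 library labelled Mafb or control library 3 (0.0779 to 0.134). Camera did not call this list (adjusted p = 0.176); 2 members fell without Mafb library 2 or 3 or control library 3. Stab1 was not called without any 1 library labelled Mafb or control library 3 (0.0545 to 0.0705), nor Scarf1 without Mafb library 2 or 3 or control library 1 or 3 (0.0622 to 0.142). Of 19 tested genes of complement C1q and efferocytosis, 5 rose (Cd36, the bridging protein Mfge8, Itgb3, Lrp1 and Dock1) and 5 fell (C1qa, Pros1, Stab1, Thbs1 and Abca7), with the same counts when adjusted over the list alone (camera adjusted p = 0.803). The median was just under 0 while the mean was 0.05 and camera pointed up, Dock1 was not called without Mafb library 3 (adjusted p = 0.0509), and 8 fell without control library 1. The 3 chains of C1q differed: C1qa fell from 304 ± 39.5 to 146 ± 2.97 FPKM (log2 fold change -1.05), while C1qb measured 968 ± 20.0 against 968 ± 23.3 and C1qc 433 ± 9.98 against 459 ± 16.5, neither past the threshold. The apoptotic cell receptor Mertk measured 24.1 ± 0.795 against 24.2 ± 4.86 FPKM (log2 fold change 0.01), and 0.16 without control library 1 (adjusted p = 0.04).

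**Figure D2:**
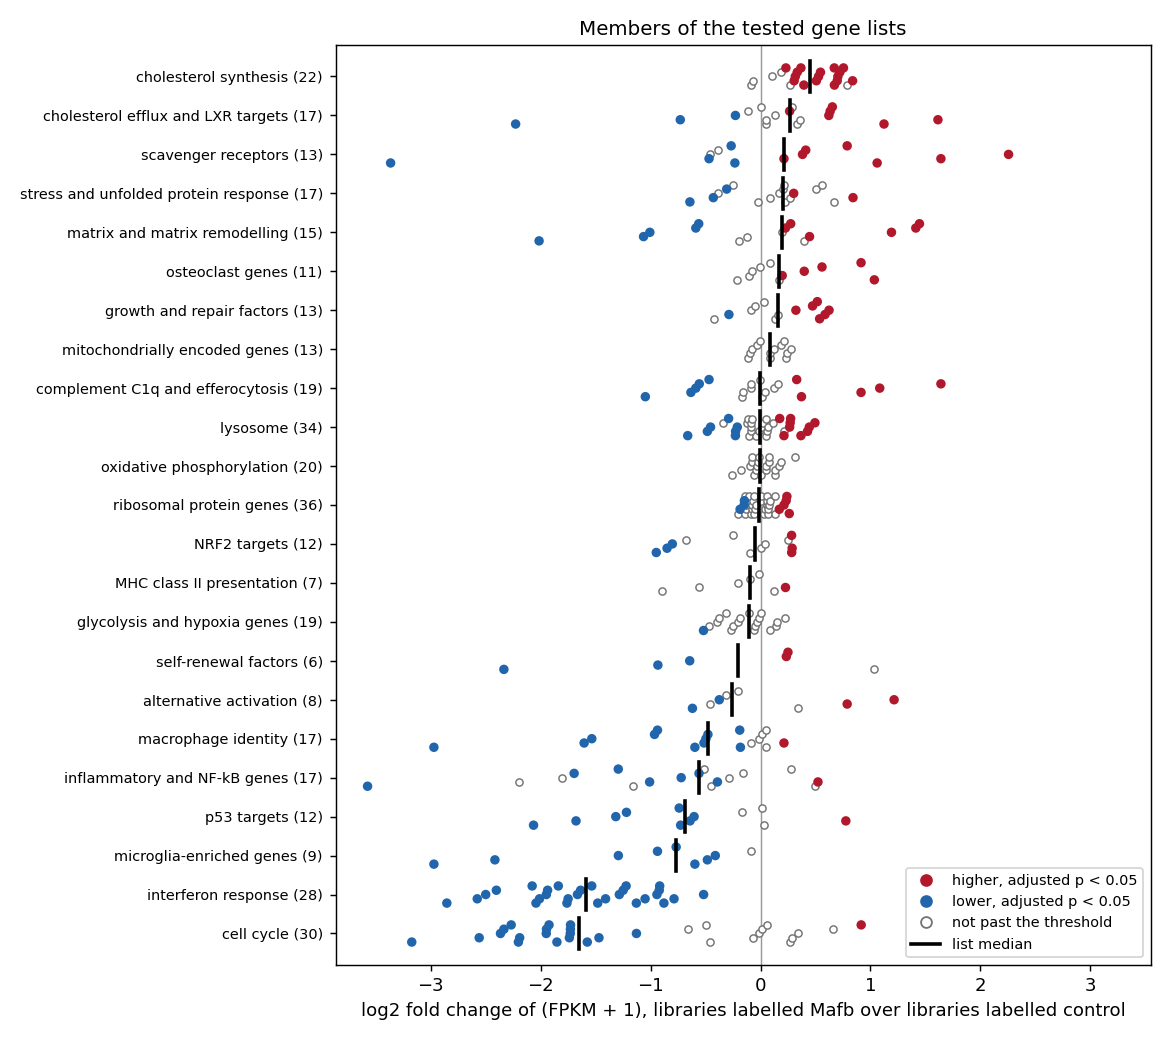
Log2 fold change of (FPKM + 1) for each tested member of the 23 tested lists, ordered by list median (black bars), with the number of members in brackets; filled points passed an adjusted p of 0.05 and open points did not. All 28 interferon response members lie below 0, the cell cycle list holds 18 members well below 0 beside a cluster near 0, and 16 of 22 cholesterol synthesis members are filled and above 0.

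Some growth and repair factors rose. Of 13 tested members 6 rose, 1 fell and 6 were not called, with the same counts when adjusted over the list alone, and the median was 0.16. Pdgfa went from 5.61 ± 0.895 to 9.12 ± 0.290 FPKM, the co-receptor Nrp1 from 28.6 to 43.4, Gdf15 from 11.2 to 16.6 and galectin-3, Lgals3, from 1525 to 2177; Vegfb fell from 20.6 to 16.7, a call lost without any 1 library labelled Mafb or control library 2 (adjusted p 0.0563 to 0.0951), while 2 members fell without control library 1 and 0 with either other scaling. Igf1 (59.2 ± 1.24 against 54.1 ± 3.90 FPKM, log2 fold change 0.13) and Vegfa (16 ± 0.509 against 16.6 ± 2.25, -0.05) did not pass, and Igf1 did at 0.18 without control library 1 (adjusted p = 0.0235). Camera gave adjusted p = 0.0073, adjusted p = 0.311 with an estimated correlation, and 0.0709 with quantile normalization.

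In the osteoclast list 5 of 11 tested members rose (Atp6v0d2, Itgb3, Tnfrsf11a, Ctsk and Ostm1) and 0 fell (6 and 0 when adjusted over the list alone, and by limma at an unadjusted p under 0.05), with a median of 0.17. The proton pump subunit Atp6v0d2 went from 157 ± 44.5 to 314 ± 6.53 FPKM and Tnfrsf11a, which encodes RANK, from 12.5 to 18.7. Camera gave adjusted p = 0.0172, and adjusted p = 0.381 with an estimated correlation. Ostm1 was not called without any 1 library except control library 1 (adjusted p 0.0551 to 0.114). The list call was also lost without control library 2 (adjusted p = 0.0601) and with quantile normalization (0.0771). The KEGG pathway of osteoclast differentiation, looked at after the data were seen, leaned the other way, with 10 of 94 genes higher and 28 lower (11 and 32 when adjusted over the list alone; median -0.09, camera adjusted p = 0.247, and 0.0478 with quantile normalization).

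Matrix remodelling genes moved apart. Of 15 tested members 6 rose and 5 fell (7 and 5 when adjusted over the list alone; camera adjusted p = 0.498). Mmp12 (131 ± 16.1 to 358 ± 2.99 FPKM), urokinase Plau (83.4 ± 23.0 to 217 ± 3.74) and its receptor Plaur (21.4 to 50.1) rose, and the collagen cross-linking enzyme Lox (22.6 ± 6.64 to 4.69 ± 0.106), Mmp14, Tgfbi, Thbs1 and Ecm1 fell. Without Mafb library 2 or 3, 3 members rose, and Tgfbi was not called without any 1 library except control library 1 (adjusted p 0.0691 to 0.0819). In the alternative activation list, Egr2 (8.56 to 21 FPKM) and the mannose receptor Mrc1 (35.8 ± 3.64 to 62.3 ± 0.883) rose, and Il10 (2.29 ± 0.512 to 1.13 ± 0.252) and Tgm2 (71.5 to 54.5) fell, out of 8 tested; adjusted over the list alone, 3 were higher and 5 lower. Camera adjusted p was 0.895, with a median of -0.26 while the mean was 0.05 and camera pointed up. Il10 was not called without Mafb library 1 (adjusted p = 0.0541), nor Tgm2 without any 1 library except control library 1 (0.0809 to 0.117). The number lower was 0 without Mafb library 1, 1 without Mafb library 2 or 3 or control library 3, and 4 without control library 1.

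Lysosomal genes went both ways: of 34 tested, 9 rose and 7 fell (9 and 8 when adjusted over the list alone; camera adjusted p = 0.674). Glb1 (65.5 to 41.0 FPKM), Hexb (232 to 166) and Grn (724 to 528) fell, and Psap rose (3892 to 5435), although not without any 1 library labelled Mafb or control library 3 (adjusted p 0.0633 to 0.0734); with quantile normalization its log2 fold change was 0.01 (adjusted p = 0.944), against 0.50 as deposited. The number that rose was 4 without any 1 library labelled Mafb, 5 without control library 3 and 15 without control library 1, and 4 fell without Mafb library 1 or 3 or after the GC content and length adjustment. The median and mean lay just under 0 while camera pointed up.

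In the stress response list, Mthfd2 (13.6 to 24.8 FPKM) and Atf3 rose and Herpud1 (17.4 to 10.8), Sesn2 and Ddit4 fell, of 17 tested (5 and 4 when adjusted over the list alone; camera adjusted p = 0.238). Atf3 was not called without any 1 library except control library 1 (adjusted p 0.0558 to 0.0878), nor Ddit4 without any except Mafb library 3 and control library 1 (0.0525 to 0.0707), nor with quantile normalization (0.0585). The number higher was 1 without any 1 library labelled Mafb or control library 3, 4 without control library 1 and 5 without control library 2, and 5 were lower without control library 1. Scaling moved the number higher as well: 5 were higher with median-of-ratios scaling, 7 with quantile normalization and 7 after the GC content and length adjustment. NRF2 targets were split, with Nqo1 (3.35 to 1.41 FPKM), Me1 and Gclm lower and Prdx1 (457 to 557), Gclc and Srxn1 higher among 12 (5 lower and 4 higher when adjusted over the list alone; camera adjusted p = 0.949). None were higher without any 1 library labelled Mafb, where Prdx1 had adjusted p 0.0721 to 0.0879, Gclc at most 0.128 (also lost without control library 3) and Srxn1 0.0663 to 0.0718. Gclm was not called without Mafb library 2 or 3 (0.0552 and 0.0584), and 5 were lower without control library 1.

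Core metabolic and housekeeping transcripts showed few differences. Of 20 oxidative phosphorylation genes 0 passed by limma over all genes or adjusted over the list alone, with 3 higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.498, pointing up, with a median just under 0 and a mean of 0.02), and 1 higher and 3 lower without control library 1. With median-of-ratios scaling and with quantile normalization 3 were higher, after the GC content and length adjustment 4, and at a mean of at least 5 FPKM 2 were lower. Atp5f1b measured 133 ± 2.91 against 117 ± 12.9 FPKM (log2 fold change 0.19, limma adjusted p = 0.137), and passed at 0.24 after the GC content and length adjustment (adjusted p = 0.0353). Of 19 glycolysis and hypoxia genes, Ankrd37 fell from 1.03 to 0.407 FPKM, and 0 passed when adjusted over the list alone, with 3 lower by limma at an unadjusted p under 0.05 (camera adjusted p = 0.631). Ankrd37 was not called without any 1 library except control library 1 (adjusted p 0.0761 to 0.12), nor with quantile normalization (0.0719). Without control library 1, in which the list's mean was 4.69 against 5.28 and 5.18 in the other controls, 13 members were lower and camera's adjusted p was 3.7e-04. Gapdh, at 5.28 to 23.1 FPKM, is uncertain because reads can be shared with copies such as Gapdh-ps15, whose mean was 28.1 FPKM.

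Of 7 tested MHC class II genes H2-DMb1 rose from 24.9 to 29.2 FPKM (1 also when adjusted over the list alone; camera adjusted p = 0.996, pointing up where the median was -0.09 and the mean -0.20); its call was lost without Mafb library 1 or 3 or control library 3 (adjusted p 0.0663 to 0.102). Without control library 1, 3 MHC class II genes were higher and 1 lower (median 0.17). Without control library 2, 1 was higher and 2 were lower (median -0.19). None of 13 mitochondrially encoded genes passed, by limma over all genes or adjusted over the list alone, with 4 higher at an unadjusted p under 0.05 (camera adjusted p = 0.142, and 0.0119 without control library 2); 4 were higher without control library 2 and 2 without control library 1. Other settings moved this count: 3 were higher with median-of-ratios scaling, 4 with quantile normalization, 5 after the GC content and length adjustment and 3 at a mean of at least 5 FPKM. The transcript mt-Co1 measured 8481 ± 155 against 9059 ± 304 FPKM. Of 36 ribosomal protein genes 5 rose and 3 fell (5 and 2 when adjusted over the list alone; camera adjusted p = 0.682), led by Rps2 (302 to 362 FPKM) and Rpl22 (26.9 to 32.0). Camera pointed up although the median was -0.02. The number higher was 1, 2 and 0 without Mafb library 1, 2 and 3, where Rps2 had adjusted p 0.0605 to 0.0895 and, without Mafb library 3, Rpl22 had 0.052. The number lower was 0 without any of these or control library 3, and 5 without control library 1. With median-of-ratios scaling 7 were higher and 0 lower, and 0 were lower after the GC content and length adjustment. Of 4 histone genes 0 passed by limma or when adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05; H1f2 measured 80.1 ± 2.32 against 90.1 ± 18.9 FPKM.

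Several genes often used to describe macrophage activation lay below the mean of 0.5 FPKM and were not tested. Arg1 measured 0 to 0.114 FPKM over the 6 libraries, Il1b 0.0412 to 0.306, Il6 0 to 0.0231 and Ccr2 0.11 to 0.228. Nos2 was listed at 0 in all 3 libraries labelled Mafb and at 0.153, 0.454 and 0.268 FPKM in controls, and Ly6c2 at 0 in 4 libraries and at 0.0326 and 0.0933 FPKM in control libraries 2 and 3.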

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

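The adjustment for GC content and length was chosen after the results were seen; the other alternatives were chosen before. The values of 114 named genes other than Mafb under the 15 refitted settings were on the same side of the threshold in 1584 of 1692 cases, past it no longer in 97, newly past it in 11 and reversed in 0.

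Genes higher numbered 2057 with quantile normalization, 2017 after adjustment for GC content and length, and 528 at an adjusted p under 0.01; genes lower numbered 1273 at a mean of at least 5 FPKM and 1150 at an adjusted p under 0.01. Fewer genes are tested at the higher mean. With pseudocounts of 0.1 and 0.01, genes at least 2-fold higher numbered 112 and 122, and genes at least 2-fold lower 532 and 563, since a smaller pseudocount widens the folds of low genes; at a mean of at least 5 FPKM 163 were at least 2-fold lower. Without single libraries, 665 to 1682 genes were higher and 1341 to 2850 lower, with the highest counts without control library 1. Mafb had a log2 fold change of 0.17 after the GC content and length adjustment, now past the threshold. The median over all genes in the fit moved up as well, from -0.04 to 0.02. The cause of the Mafb change was not tested.

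With an estimated correlation none of the list calls held, by adjusted p: cell cycle 0.798, cholesterol efflux and LXR targets 0.381, cholesterol synthesis 0.311, growth and repair factors 0.311, inflammatory cytokines and NF-kB genes 0.419, interferon response 0.309, macrophage identity 0.188, microglia-enriched genes 0.309, osteoclast genes 0.381 and p53 targets 0.188. With quantile normalization the calls of cholesterol efflux and LXR targets (0.12), growth and repair factors (0.0709) and osteoclast genes (0.0771) were lost. With fry, the cell cycle list had 0.0571 and scavenger receptors 2.6e-04; fry asks whether a list moves on balance one way, not whether it differs from other genes. Leaving out single libraries gave adjusted p of 3.7e-04 to 0.925 for glycolysis and hypoxia genes, 0.0119 to 0.243 for mitochondrially encoded genes and 0.00115 to 0.0601 for osteoclast genes. The causes of these changes were not tested. Without the filter on low values, members called higher numbered 3 in the lysosome list, 1 among NRF2 targets, 3 among ribosomal protein genes, 1 in the stress response list and 0 in the macrophage identity list. Members called lower numbered 6 in the macrophage identity list, 2 among scavenger receptors, 1 among LXR targets, 2 among G1/S genes and 0 in the alternative activation, ribosomal protein, glycolysis and growth factor lists. Lists that gained tested members there had 4 higher stromal markers, 1 higher microglia-enriched and 1 higher monocyte gene, and lower, 2 MHC class II genes, 1 neutrophil marker and 1 osteoclast gene. At a mean of at least 5 FPKM 10 of 18 tested cell cycle genes, 10 of 15 G2/M genes, 4 of 5 microglia-enriched genes, 1 of 9 NRF2 targets, 1 of 5 alternative activation genes and 0 of 11 G1/S genes were lower. Without the intensity trend 3 ribosomal protein genes were higher and 1 lower. The list of self-renewal factors had fewer than 5 members at a mean of at least 5 FPKM and no value there.

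The replicate numbers gave little sign of pairing: deviations of libraries with the same number correlated at 0.00874, 0.021 and 0.0505. Number 1 correlated more with another number (0.0195). Numbers 2 and 3 correlated most with their own (highest with another number -0.00646 and -0.00183). With the number as a replicate block 980 genes were higher and 1699 lower, and no list call and no Mafb call changed. Among named genes it ended the calls of Maf (adjusted p = 0.0754), Tgm2 (0.0706), H2-DMb1 (0.0707), Prdx1 (0.0522), Kitl (0.0742) and Rps2 (0.0565), and Myc passed (0.048). Members called higher then numbered 5 in the lysosome list, 3 in the matrix list, 2 among ribosomal protein genes and 1 among NRF2 targets, and 1 ribosomal protein gene and 1 alternative activation gene were lower. FPKM without counts leaves the depth in reads unknown, which limits statements on low genes.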

Other observations

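The pathway test, the G2/M and G1/S lists, the adjustment for GC content and length, the tests on the Mafb row, on the virus preparations, on control library 1 and on G1/S genes, and the count of splits were chosen after results were seen.

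Beyond the fixed lists, 20 of 309 KEGG pathways of 10 to 300 tested genes were called by camera at the preset correlation, 6 higher and 14 lower in the libraries labelled Mafb, and 0 of those 20 with an estimated correlation. Ribosome biogenesis was higher, with 18 of 71 genes up and 3 down (18 and 4 when adjusted over the list alone; Benjamini-Hochberg adjusted p = 0.0011, and adjusted p = 0.977 with an estimated correlation). Aminoacyl-tRNA biosynthesis was higher too, with 9 of 44 up and 3 down, also 9 and 3 when adjusted over the list alone (adjusted p = 0.0049, and adjusted p = 0.977 with an estimated correlation). RIG-I-like receptor signaling, a pathway that senses viral RNA, was lower, with 23 of 45 genes down and 2 up (25 and 2 when adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.977 with an estimated correlation).

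Single genes outside the lists, chosen after their values were seen, differed as well. The mycobacterial glycolipid receptor Clec4e measured 2.58, 2.96 and 3.00 FPKM in the libraries labelled Mafb and 21.6, 27.9 and 22.4 in controls (log2 fold change -2.69, limma adjusted p = 3.0e-05), and its neighbour Clec4n had a log2 fold change of -2.30. The RNA sensor Tlr7 had -1.13, while Tlr4 had -0.09 and did not pass (adjusted p = 0.163). Pparg, a nuclear receptor of lipid metabolism, was higher (log2 fold change 1.22, adjusted p = 0.002), at 20.8, 20.7 and 22.4 FPKM against 11.5, 7.26 and 7.41, as was the transferrin receptor Tfrc (1.21, adjusted p = 3.7e-05). The interferon receptor subunits Ifnar1 (-0.16, adjusted p = 0.117) and Ifnar2 (0.01, adjusted p = 0.932) did not pass. The 3 libraries labelled Mafb were closer to each other than the controls were, with a lowest correlation of 0.993 against 0.982.

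The Mafb row was nearly level while 3389 genes were called. A single library in the wrong group is argued against: for each of the 6 libraries the lowest correlation within its group exceeded the highest with the other group, by at least 0.013. Exchanged labels of the whole groups cannot be told apart from correct ones by this row, because its log2 fold change of 0.097 is too small to check either. A vector transcript that was not counted in the Mafb row may also be at work. That stays open because 0 rows of the table are other than mouse Ensembl genes. As counted, the row does not show Mafb overexpression (ratio 1.07, 95% interval 0.991 to 1.15). Little or no overexpression at harvest stays open too, so the 3389 calls cannot be credited to raised Mafb RNA. Mafb protein was not analysed here.

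For the lower interferon response, scaling between libraries is argued against, since 28 of 28 members were called lower under both other scalings. GC content and transcript length as the whole cause are argued against by a list median of -1.52 after that adjustment, and a single library by at least 26 of 28 members called without each. Unequal activation of the cells by the virus preparations cannot be told apart from an effect of Mafb, because each group had its own virus. The inflammatory list leaned lower (median -0.56, camera adjusted p = 0.0083 at the preset correlation, fry adjusted p = 0.0041). With an estimated correlation its camera adjusted p was 0.419. None of the 23 lists was called in that setting, so that value decides nothing. Either origin could lower this list. An effect of Mafb on interferon-induced genes is thus a hypothesis that these data leave open.

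The lower mitotic transcripts extended to genes outside the fixed list: 33 of 39 G2/M genes fell (34 lower and 1 higher when adjusted over the list alone; median -1.32, camera p = 6.5e-13, and p = 0.191 with an estimated correlation). Control library 1 as the sole cause is argued against, since the mean over these genes in the other controls lay at least 1.34 above every library labelled Mafb on the log2(FPKM + 1) scale, with control library 1 in between, and so is scaling, with 33 of 33 called under both other scalings. Fewer cells in every phase of the cycle cannot be excluded: the median of 31 tested G1/S genes was -0.0791 (SD 0.41 over genes; 2 higher and 6 lower, also when adjusted over the list alone), but -0.22 (SD 0.43; 2 higher and 14 lower) without control library 1 and 0.03 (2 lower) without control library 2. The number lower was also 2, 1 and 1 without Mafb libraries 1, 2 and 3, and 2 without control library 3. With quantile normalization it was 4 (median 0.02). A fall as deep as that of the G2/M genes (median -1.53 without control library 1) is argued against for these G1/S genes. They do not decide on a smaller fall in every phase. Pcna rose, and no Mcm gene named above passed. In the KEGG DNA replication pathway 5 of 35 genes were higher and 0 lower (4 and 0 when adjusted over the list alone, median 0.006, camera adjusted p = 0.463). Fewer cells in G2 and mitosis in the cultures labelled Mafb is a hypothesis that DNA content per cell, not analysed here, could test; an effect of Mafb and a difference between the virus preparations are both open as its origin.

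Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real one, namely the real split itself with 3389; the highest of the others was 1. With 10 splits no share under 0.05 can be reached.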
